A study of Mus musculus with 66 samples.

How the data were processed

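RNA sequencing values of 66 libraries were analysed. They came from 3T9-MycER cells, a line of mouse embryonic fibroblasts with floxed alleles of c-myc that had been infected with a retroviral MycER construct. MycER is the transcription factor Myc fused to the ligand-binding part of the oestrogen receptor, and 4-hydroxytamoxifen (OHT) makes it active. Cells received 400 nM OHT for 10 min, 20 min, 30 min, 1 h, 1.5 h, 2 h, 4 h, 8 h, 12 h or 16 h, or were taken at 0 min. Each time had 3 libraries of RNA labelled for 10 min with 300 µM 4-thiouridine (4sU), which enters newly made RNA, and 3 libraries of total RNA. Per the labels' protocols, labelled RNA was biotinylated and bound to streptavidin beads. Groups and replicate numbers came from the sample titles, and table columns were matched to samples by RNA kind, time and replicate number. The labels name no separate cultures behind the replicate numbers, so p-values measure the spread between these libraries, which may be technical. The series has no time course without OHT, and the 0 min libraries were the control for every time.

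TopHat2 2.0.8, TopHat and the mouse genome build mm9 are named in the submitters' processing notes without their roles. The counting tool, the gene annotation and whether counting used strand are not given in the sources used here. The authors deposited 8 tables of 11513 genes each, with exon and intron values kept apart, as tables named counts and tables of RPKM. The files give Entrez identifiers with symbols, and 15 genes had no symbol. The values the authors deposited as counts are whole numbers but not raw counts, and they were treated as a score with no count model. In 13 of the 66 libraries some whole numbers from 2 to 28 were nearly missing (under 20% of the mean of both neighbours, where that mean was at least 20), as after multiplying by a factor and rounding, with 5 such numbers in replicate 2 of labelled RNA at 1 h. The RPKM values the authors deposited are the same values times 1 constant per gene, with a largest deviation of 0.0049% between libraries. True read depth is therefore unknown. The deposited sums per library were (in units of 1e6) 11.62 to 14.12 for labelled exons, 31.28 to 39.26 for labelled introns, 46.5 to 52.72 for total exons and 10.65 to 13.01 for total introns. No interval that needs a read number is given.

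The design chosen before the data were examined assumed raw counts, and its count model was replaced because the values turned out to be rescaled. The same comparisons, samples and covariates were kept. Each table was scaled by trimmed means of log ratios, with 30% of the log ratios and 5% of the mean levels trimmed at each end. The scaling factors lay between 0.9214 and 1.082. Genes with a value of at least 10 in at least 3 libraries were kept. A linear model with 1 mean per time over all 33 libraries of a table was fitted to log2(scaled value + 1) with limma 3.58.1 in R 4.3.3, with a trend of the variance over the mean level. All tests were two-sided with Benjamini-Hochberg adjustment, and calls had an adjusted p under 0.05. Log2 changes are on the log2(value + 1) scale, which understates the change of genes with low values. Means and SDs of single genes are scaled deposited values over 3 libraries per group, and ± after a log2 change is its standard error. The main times were 1 h, 4 h and 16 h in labelled and total exons, and 4 h in introns. The change in labelled RNA was compared with that in total RNA as an interaction over all 66 libraries. The intron to exon ratio was tested within each labelled library, with a pseudocount of 2.

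A rule fixed before the data were examined chose the genes named for the main exon comparisons. For labelled exons at 1 h, 4 h and 16 h and total exons at 4 h and 16 h it took the 8 called genes with the largest rise and the 8 with the largest fall. They needed a mean of at least 50 in the higher group, groups that did not overlap and a curated symbol. Statements of the largest rise or fall cover the genes that met these conditions. The rule added up to 4 members per gene list with the smallest p, and always Myc, Ncl, Odc1, Cad, Cdk4, Ccnd2 and Cdkn1a. Some results that the rule covers are not reported here. Genes named outside the rule are said to have been chosen after their values were seen. Genomic positions are from the GENCODE M1 annotation of the mm9 genome.

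There were 28 gene lists fixed before the data were examined, and 27 of them had 3 or more measured members. They covered ribosome biogenesis, RNA polymerases I and III, cytosolic tRNA synthetases, purine and pyrimidine synthesis, polyamine synthesis, serine and one-carbon metabolism, amino acid transporters, cytosolic ribosomal proteins and translation initiation and elongation factors. Further lists held the CCT chaperonin and mitochondrial chaperones, the mitochondrial ribosome and transcription, glycolysis and lactate, G1/S and DNA replication, mitosis, replication-dependent histones and the Myc network. The others held CDK inhibitors and growth arrest genes, p53 targets, extracellular matrix genes and TGF-beta targets, actomyosin and adhesion genes, immediate early genes, sterol synthesis and uptake, the integrated stress response, the unfolded protein response, heat shock genes, the circadian clock, interferon-stimulated genes and markers of other cell types. Each list was set against all other genes with camera in limma at a preset correlation of 0.01, and again with a correlation estimated from the data. Benjamini-Hochberg adjustment ran over the 162 tests of 27 lists in 6 comparisons. With the preset correlation 65 of the 162 tests were called, 51 up and 14 down, and 9 of the 65 were also called with an estimated correlation. List members belong to shared regulatory programmes, so the p with an estimated correlation is printed where the call was lost. With the preset correlation, another grouping of the same libraries called more lists than the real one in every comparison except labelled exons at 1 h.

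The models were tested on simulated data with 200 changed genes, made from the spread of each table. In the real comparisons at 4 h, limma called 38.3% of genes in labelled exons and 39.4% in total exons. Recovery with that many changed genes was not simulated, so the shares below are not the sensitivity in the real comparisons. For labelled exons at 4 h, over 11435 genes, 33.8% of genes changed by 0.3 on the log2 scale were recovered, 69.7% of those changed by 0.5 and 93.9% of those changed by 1. Of the 140 genes called there, 9 were false. For total exons at 4 h, over 11429 genes, the shares were 42.6%, 72.7% and 92.4%, with 11 false among 149 called. In simulated lists on labelled exons at 4 h, 10 of 10 lists shifted by 0.3 were recovered and 0 unshifted lists were called by camera. Their genes were drawn independently, so the simulated lists do not test camera on members that move together. The correlation estimated for ribosome biogenesis in labelled exons was 0.324.

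Replicate numbers were checked for pairing by correlating deviations from the group means over genes. Among the main comparisons, in total RNA at 4 h against 0 min every same-numbered pair had a correlation above 0.1, at 0.331, 0.31 and 0.22 for exons and 0.25, 0.143 and 0.116 for introns, so there the numbers were taken to pair the libraries. They were also above 0.1 in total exons at 10 min, 20 min, 30 min, 2 h and 8 h, in labelled exons at 8 h and, at the limit, in total introns at 10 min. The pairing comes from these data, not from the labels. The main fits had no replicate block, in total RNA at 4 h too, and the fit with the block was an alternative. Labelled and total libraries of the same number deviated together at 4 h and 16 h, so a fit with those pairs was added after seeing the data. Alternatives were other scalings, pseudocounts, filters and weights, the RPKM values, a replicate block, fits of the compared libraries alone and leaving out single libraries.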

Results

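The data are a time course of gene expression after activation of MycER by OHT in mouse 3T9-MycER fibroblasts, measured in newly made, 4sU-labelled RNA and in total RNA. Each of the 11 times from 0 min to 16 h had 3 libraries of labelled and 3 of total RNA. Introns took 69.1% to 75.9% of the deposited sum of a labelled library and 17.1% to 21.5% of that of a total RNA library. The 10 genes with the highest exon values held 2.94% to 3.47% of the exon sum in labelled RNA and 4.79% to 6.03% in total RNA. Changes are against 0 min and relative to the typical gene of a library, because no spike-in is described and a general rise or fall of all RNA cannot be seen.

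The comparison at 1 h asked which genes changed their newly made RNA early after Myc activation. Nr1d1, which encodes the nuclear receptor REV-ERBα that represses circadian clock genes, had the largest rise in labelled exons. Its level (Entrez 217166, chromosome 11 from 98629246 to 98636647 in mm9) went from 299.1 ± 44.5 to 2006 ± 162 (mean ± SD, n = 3 per group), a log2 change of 2.75 ± 0.11 (limma adjusted p = 1.43e-19). P2ry2, a purinergic receptor (Entrez 18442, chromosome 7 from 108145086 to 108160505), rose by 2.63 ± 0.23 (adjusted p = 6.55e-11), the zinc exporter gene Slc30a1 by 2.38 ± 0.13 and Dusp2, a MAP kinase phosphatase, by 2.21 ± 0.13. Spry1, an inhibitor of receptor tyrosine kinase signalling, the small GTPase gene Rasl11a, the sialyltransferase gene St6galnac4 and the coactivator gene Ppargc1b rose by 2.19, 2.10, 2.02 and 1.94. Falls were smaller, the largest being in Ccng2, an unconventional cyclin linked to growth arrest (Entrez 12452, chromosome 5 from 93696283 to 93705257). Ccng2 fell by 1.34 ± 0.16 (adjusted p = 1.02e-07) from 416.9 ± 26.5 to 165 ± 27.5, the zinc finger genes Zfp40 and Zscan21 fell by 1.29 ± 0.16 and 1.07 ± 0.17, and Rgs12, a regulator of G protein signalling, fell by 1.04 ± 0.16. Dnajb5 and Paqr5 also fell, by 1.11 ± 0.23 and 1.21 ± 0.24. Of the always named genes, Ncl, which encodes the nucleolar protein nucleolin, rose by 0.34 ± 0.09 (adjusted p = 0.00695) and the cyclin gene Ccnd2 by 0.61. The call of Ncl ended without further scaling of the deposited values (0.0511), with RPKM plus 0.1 (0.0545) and with RPKM plus 1 (0.0534). Odc1, Cdk4, Cdkn1a and Myc did not pass the test, with changes of 0.18, 0.19, -0.72 and -0.24, and Cad, an enzyme of pyrimidine synthesis, had a change of 0.25 with an adjusted p of 0.0228. That call of Cad ended with scaling by library sums (0.0673), without further scaling (0.12), with RPKM plus 0.1 (0.132) and RPKM plus 1 (0.136), and without replicate 2 at 0 min (0.193) or replicates 1 and 3 at 1 h (0.124 and 0.0586). By limma, 1574 of 11488 genes rose and 1109 fell, or 1230 and 1575 with scaling by library sums.

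Ribosome biogenesis genes rose together at 1 h in labelled exons, with 26 of 40 measured members up and 0 down (32 and 0 adjusted over the list alone). The U3 ribonucleoprotein gene Rrp9 rose by 1.01 ± 0.08 and Ddx10 and Rrp1b by 0.77 and 0.76. The camera adjusted p was 2.67e-14, and the adjusted p = 0.116 with an estimated correlation. Genes for RNA polymerases I and III had 17 up and 0 down of 33 (18 and 2 adjusted over the list alone, adjusted p = 2.99e-05, and adjusted p = 0.0645 with an estimated correlation). Taf1c rose by 0.94 and Polr1e by 0.78. Amino acid transporters had 8 up and 0 down of 16 (9 and 0 adjusted over the list alone, adjusted p = 2.92e-06, and adjusted p = 0.0377 with an estimated correlation). Slc7a1 and Slc1a5 rose by 0.78 and 0.73. The list also holds Slc16a1, a monocarboxylate transporter gene, which rose by 0.80. The circadian clock list had 9 up and 0 down of 17 (9 and 0 adjusted over the list alone, adjusted p = 8.25e-07, and adjusted p = 0.043 with an estimated correlation). Bhlhe41 and Bhlhe40, which encode repressors of clock transcription, rose by 1.90 and 1.08 and Nr1d2, the paralog of Nr1d1, by 0.97. Mitosis genes fell, with 1 up and 16 down of 29 (1 and 17 adjusted over the list alone, adjusted p = 1.5e-07, and adjusted p = 0.0728 with an estimated correlation). Kif2c, Cenpe and Top2a changed by -0.50, -0.44 and -0.33.

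Further shifts at 1 h in labelled exons came from metabolic and translation lists. Purine and pyrimidine synthesis had 11 up and 1 down of 27 (12 and 1 adjusted over the list alone, adjusted p = 0.00488, and adjusted p = 0.307 with an estimated correlation). Ppat, the first enzyme of purine synthesis, rose by 0.76 ± 0.07. Translation factors had 14 up and 1 down of 37 (14 and 1 adjusted over the list alone, adjusted p = 0.000109, and adjusted p = 0.364 with an estimated correlation). The cap-binding factor gene Eif4e rose by 0.42. Mitochondrial ribosome and transcription genes had 11 up and 0 down of 35 (12 and 0 adjusted over the list alone, adjusted p = 0.00377, and adjusted p = 0.206 with an estimated correlation). Tfb2m, a mitochondrial transcription factor gene, rose by 0.84 ± 0.08. Chaperonins and mitochondrial chaperones had 6 up and 0 down of 22 (6 and 0 adjusted over the list alone, adjusted p = 0.00423, and adjusted p = 0.41 with an estimated correlation). Tomm20 rose by 0.35. Serine and one-carbon metabolism had 8 up and 3 down of 16 (9 and 3 adjusted over the list alone, adjusted p = 0.0173, and adjusted p = 0.206 with an estimated correlation). Mat2a and Mthfd1l rose by 0.53 and 0.49. Cytosolic ribosomal proteins had a median change of 0.11 with 3 up and 0 down of 51 (0 and 0 adjusted over the list alone), called at an adjusted p of 0.00601, which became 0.0827 without replicate 2 at 1 h, and the adjusted p = 0.67 with an estimated correlation. Polyamine synthesis had 4 up and 0 down of 10 (4 and 0 adjusted over the list alone, adjusted p = 0.027, and adjusted p = 0.206 with an estimated correlation), and the Myc network 4 up and 1 down of 10 (4 and 1 adjusted over the list alone, adjusted p = 0.0275, and adjusted p = 0.155 with an estimated correlation), with the Myc partner gene Max up by 0.76. Without replicate 2 at 0 min these became 0.0528 for polyamine synthesis and 0.0654 for the Myc network, and without further scaling 0.0521 for polyamine synthesis. Glycolysis and lactate genes had 2 up and 0 down of 20 (2 and 0 adjusted over the list alone, adjusted p = 0.315), namely Hk2 at 1.02 and Pfkfb3 at 0.90. Immediate early genes had 3 up and 0 down of 24 (3 and 0 adjusted over the list alone) and a median of 0.29 (adjusted p = 0.0519).

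By 4 h the same direction held in labelled exons for P2ry2 and St6galnac4, which had risen by 3.12 ± 0.23 and 2.69 ± 0.08. Rgcc, a regulator of the cell cycle, rose by 3.48 ± 0.41 from 5.767 ± 0.721 to 76.21 ± 22.2 (n = 3 per group, limma adjusted p = 1.91e-08), a fold that depends on the pseudocount because the 0 min value is low. Ankrd6, an ankyrin repeat protein, rose by 2.61 ± 0.16, and Il15ra, the alpha chain of the interleukin 15 receptor, by 2.38 ± 0.14. Ccng2 fell by 2.40 ± 0.16 to 78.21 ± 5.87 (adjusted p = 6.86e-14). Arntl, which encodes the clock activator BMAL1 (Entrez 11865, chromosome 7 from 120350979 to 120457636), fell by 2.01 ± 0.17 from 674 ± 157 to 165.9 ± 31.8 (adjusted p = 2.11e-11). Tgfb1i1, which encodes the focal adhesion protein Hic-5 (Entrez 21804, chromosome 7 from 135390326 to 135398287), fell by 1.77 ± 0.17 (adjusted p = 4.36e-10), and Rgs12 by 1.43 ± 0.16. Ncl, Cad and Ccnd2 rose by 0.50, 0.46 and 0.85, and Odc1 rose by 0.33. The call of Odc1 ended with RPKM plus 0.1 (0.0554) and RPKM plus 1 (0.0568). Cdk4 and Myc did not pass the test with changes of 0.04 and -0.14. Cdkn1a, which encodes the cyclin-dependent kinase inhibitor p21, was low and fell by 1.60 (adjusted p = 0.00113). In all, 2247 genes rose and 2155 fell, or 1669 and 2584 without further scaling of the deposited values.

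Among the lists at 4 h in labelled exons, ribosome biogenesis had 32 up and 0 down of 40 (35 and 0 adjusted over the list alone, adjusted p = 2.17e-14, and adjusted p = 0.115 with an estimated correlation). Rrp9 rose by 1.5 and Ebna1bp2 by 0.74. RNA polymerases I and III had 19 up and 2 down of 33 (20 and 2 adjusted over the list alone, adjusted p = 3.99e-07, and adjusted p = 0.0263 with an estimated correlation). Taf1c rose by 1.24 and Polr1b by 0.94. The mitochondrial ribosome and transcription list had 16 up and 0 down of 35 (17 and 0 adjusted over the list alone, adjusted p = 3.42e-05, and adjusted p = 0.0728 with an estimated correlation). Tfb2m rose by 1.14 and Mrpl16 by 0.84. Amino acid transporters had 9 up and 1 down of 16 (9 and 1 adjusted over the list alone, adjusted p = 0.000308, and adjusted p = 0.0847 with an estimated correlation). Translation factors had 17 up and 0 down of 37 (17 and 0 adjusted over the list alone, adjusted p = 0.000617, and adjusted p = 0.403 with an estimated correlation), chaperonins and mitochondrial chaperones 9 up and 0 down of 22 (9 and 0 adjusted over the list alone, adjusted p = 0.00889, and adjusted p = 0.446 with an estimated correlation). Purine and pyrimidine synthesis had 12 up and 4 down of 27 (14 and 5 adjusted over the list alone, adjusted p = 0.01, and adjusted p = 0.364 with an estimated correlation). Mitosis genes had 2 up and 21 down of 29 (2 and 22 adjusted over the list alone, adjusted p = 8.89e-06, and adjusted p = 0.115 with an estimated correlation). Cenpe changed by -0.61 and Ccnb2 by -0.55. Actomyosin and adhesion genes had 0 up and 14 down of 26 (0 and 15 adjusted over the list alone, adjusted p = 1.51e-05, and adjusted p = 0.206 with an estimated correlation). The integrin gene Itga3 changed by -0.42 and the filamin gene Flna by -0.39. Extracellular matrix genes and TGF-beta targets had 1 up and 13 down of 33 (2 and 13 adjusted over the list alone, adjusted p = 0.004, and adjusted p = 0.206 with an estimated correlation). Lox, which crosslinks collagen, and Thbs1 both changed by -0.51. The G1/S and DNA replication list went both ways with 11 up and 10 down of 39 (12 and 11 adjusted over the list alone, adjusted p = 0.994, median -0.01 and mean 0.03), with the cyclin gene Ccne1 at 0.61 and Cdk2 at -0.63. The clock list had 8 up and 5 down of 17 (10 and 5 adjusted over the list alone, adjusted p = 0.52).

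At 16 h Klhdc8a, a kelch domain gene, had the largest fall in labelled exons. It fell by 2.74 ± 0.15 from 627.6 ± 43.8 to 93.9 ± 16.5 (n = 3 per group, limma adjusted p = 7.46e-17), Tgfb1i1 by 2.66 ± 0.17 and Tinagl1, a matrix-associated protein gene, by 2.64 ± 0.11 (adjusted p = 6.65e-20). The connexin gene Gjb2 fell by 2.64 ± 0.31, the tight junction gene Cldn1 (Entrez 12737, chromosome 16 from 26356728 to 26371927) by 2.55 ± 0.17 and Fblim1, a filamin-binding adhesion protein gene, by 2.28 ± 0.16. The largest rise was in Slc38a3, an amino acid transporter gene, from 1.555 ± 1.92 to 69.23 ± 17.8, whose log2 change of 5.03 ± 0.69 depends on the pseudocount. Rgcc, Ankrd6 and Smpdl3b rose by 4.19 ± 0.41, 2.91 ± 0.16 and 2.88 ± 0.13, and Dgat2, an enzyme of triglyceride synthesis, by 2.35 ± 0.16. Myc exon values, which may hold reads of the endogenous gene and of the fusion gene, fell by 1.27 ± 0.16 from 3321 ± 591 to 1395 ± 382 (adjusted p = 6.5e-08). Myc intron values fell as well, by 1.17 ± 0.19 in labelled RNA and 1.20 ± 0.13 in total RNA (limma adjusted p = 5.75e-06 and 4.67e-09). The intron values were picked after they were seen, and how the exon fall divides between the 2 genes was not tested. In labelled exons Ncl, Odc1, Cad and Ccnd2 rose by 0.64, 0.57, 0.69 and 0.64, and Cdk4 did not pass the test at 0.10. Cdkn1a stood at -1.23 with an adjusted p of 0.0088. It became 0.052 without replicate 3 at 0 min and 0.0536 and 0.102 without replicates 1 and 3 at 16 h. In all, 2615 genes rose and 2479 fell.

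Actomyosin and adhesion genes fell in 26 of 26 members at 16 h in labelled exons (26 adjusted over the list alone, adjusted p = 6.01e-19, and adjusted p = 0.0134 with an estimated correlation). Their median was -0.92, and Itga3, the calponin gene Cnn2 and Flna changed by -1.35, -1.14 and -1.10. Extracellular matrix genes and TGF-beta targets had 0 up and 26 down of 33 (0 and 26 adjusted over the list alone, adjusted p = 7.42e-12, and adjusted p = 0.00684 with an estimated correlation). The collagen genes Col1a1 and Col5a1 changed by -1.5 ± 0.13 and -1.33 ± 0.07 and Thbs1 by -1.72 ± 0.12. The mitochondrial ribosome and transcription list had 29 up and 0 down of 35 (30 and 0 adjusted over the list alone, adjusted p = 2.25e-09, and adjusted p = 0.0134 with an estimated correlation). Tfb2m rose by 1.21 and Mrpl16 by 0.98. Ribosome biogenesis had 32 up and 0 down of 40 (35 and 0 adjusted over the list alone, adjusted p = 1.24e-12, and adjusted p = 0.154 with an estimated correlation) and RNA polymerases I and III 22 up and 1 down of 33 (22 and 2 adjusted over the list alone, adjusted p = 5.93e-06, and adjusted p = 0.043 with an estimated correlation). Chaperonins and mitochondrial chaperones had 20 up and 0 down of 22 (21 and 0 adjusted over the list alone, adjusted p = 1.85e-06, and adjusted p = 0.166 with an estimated correlation). Timm8a1 and Hspd1 rose by 0.76 and 0.59. Heat shock genes had 9 up and 0 down of 16 (9 and 0 adjusted over the list alone, adjusted p = 0.000909, and adjusted p = 0.128 with an estimated correlation). The HSP90 gene Hsp90aa1 rose by 0.71 and its co-chaperone gene Fkbp4 by 0.86. Translation factors had 16 up and 3 down of 37 (17 and 3 adjusted over the list alone, adjusted p = 0.000375, and adjusted p = 0.398 with an estimated correlation), and purine and pyrimidine synthesis 17 up and 2 down of 27 (17 and 2 adjusted over the list alone, adjusted p = 0.000952, and adjusted p = 0.206 with an estimated correlation). Amino acid transporters had 9 up and 2 down of 16 (9 and 2 adjusted over the list alone, adjusted p = 0.039, and adjusted p = 0.345 with an estimated correlation), a call that ended without replicate 2 at 0 min (0.0528) or replicate 3 at 16 h (0.0649).

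Immediate early genes had 3 up and 14 down of 24 at 16 h in labelled exons (4 and 15 adjusted over the list alone, adjusted p = 0.0148, and adjusted p = 0.543 with an estimated correlation). Maff and Arc changed by -1.26 and -1.14, while Dusp2 rose by 1.95. Without replicate 3 at 16 h the adjusted p was 0.0545. Mitosis genes, which had fallen at 1 h and 4 h, had 10 up and 4 down of 29 (10 and 5 adjusted over the list alone, adjusted p = 0.454), with Bub1b at 0.49. CDK inhibitors and growth arrest genes had 2 up and 8 down of 16 (2 and 8 adjusted over the list alone, adjusted p = 0.159), with Gadd45g and the antiproliferative gene Btg2 at -1.93 and -1.16. The p53 target list had 6 up and 6 down of 22 (adjusted p = 0.988), sterol synthesis and uptake 4 up and 3 down of 25 (adjusted p = 0.703), glycolysis and lactate 5 up and 5 down of 20 (adjusted p = 0.865), the integrated stress response 3 up and 2 down of 12 (adjusted p = 0.886), the unfolded protein response 2 up and 3 down of 19 (adjusted p = 0.521) and interferon-stimulated genes 0 up and 1 down of 8 (adjusted p = 0.338). Cytosolic tRNA synthetases had 8 up and 2 down of 20 (adjusted p = 0.136). Of 25 replication-dependent histone genes only Hist1h2bc was measured, with changes in labelled exons of 0.28 at 1 h and 4 h and 0.47 at 16 h. The call at 16 h ended with RPKM plus 0.1 (0.0526) and RPKM plus 1 (0.0539) and without replicate 2 at 0 min (0.204) or replicates 1 and 2 at 16 h (0.071 and 0.125). The median, the mean and the direction of the test differed in sign for some uncalled lists. They were p53 targets, the unfolded protein response and interferon-stimulated genes at 1 h, G1/S and the integrated stress response at 4 h, and the Myc network and the integrated stress response at 16 h. In total exons they were interferon-stimulated genes at 1 h, the Myc network, the integrated stress response and heat shock genes at 4 h, and mitosis and the Myc network at 16 h.

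**Figure D1:**
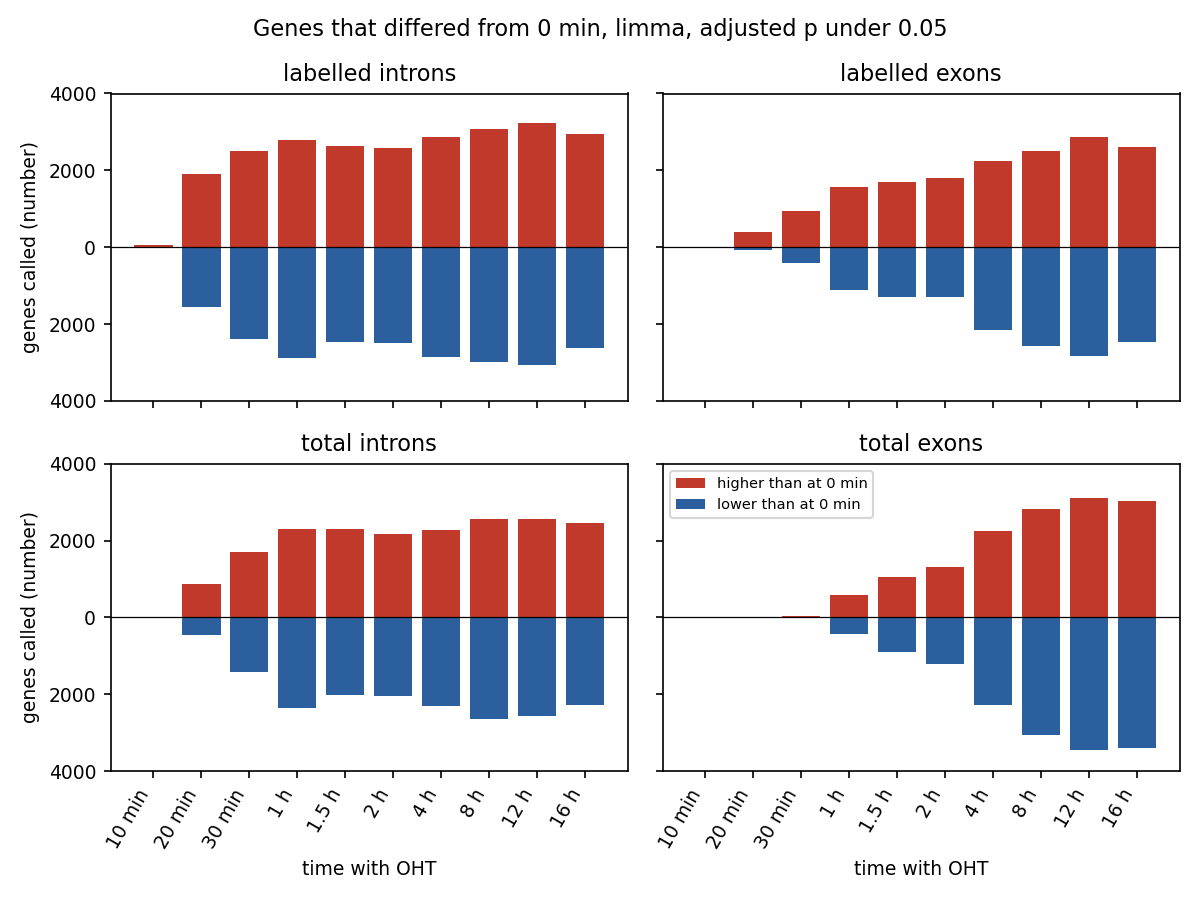
Number of genes called by limma at an adjusted p under 0.05 against 0 min, counted up and down (y axis) at each time after OHT (x axis, times as categories and not to scale), in labelled and total exons and introns. At 20 min labelled introns had 3469 called genes and total exons 5.

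In total RNA the first hour brought fewer called genes than in labelled RNA, and clock genes were among those that rose. Nr1d1 rose by 2.94 ± 0.14 in total exons at 1 h, from 485.9 ± 116 to 3677 ± 139 (n = 3 per group, limma adjusted p = 4.64e-15), Bhlhe41 by 2.08 and Bhlhe40 by 0.97. The clock list had 9 up and 0 down of 17 (11 and 0 adjusted over the list alone, adjusted p = 1.99e-10, and adjusted p = 0.00223 with an estimated correlation). Amino acid transporters had 8 up and 0 down of 16 (8 and 0 adjusted over the list alone, adjusted p = 2.29e-06, and adjusted p = 0.0412 with an estimated correlation). Slc1a5 rose by 0.46. Ribosome biogenesis had 13 up and 0 down of 40 (18 and 0 adjusted over the list alone, adjusted p = 1.72e-11, and adjusted p = 0.206 with an estimated correlation). Rrp1b rose by 0.53. RNA polymerases I and III had 13 up and 0 down of 33 (13 and 0 adjusted over the list alone, adjusted p = 7.15e-07, and adjusted p = 0.0728 with an estimated correlation). Polr1e rose by 0.44. Immediate early genes had 2 up and 0 down of 24 (3 and 0 adjusted over the list alone, adjusted p = 0.000975, and adjusted p = 0.403 with an estimated correlation). Dusp2 rose by 2.06 ± 0.10. Mitosis genes had 0 up and 3 down of 29 (0 and 6 adjusted over the list alone, adjusted p = 0.00198, and adjusted p = 0.425 with an estimated correlation) and translation factors 6 up and 1 down of 37 (8 and 1 adjusted over the list alone, adjusted p = 0.00198, and adjusted p = 0.425 with an estimated correlation). Purine and pyrimidine synthesis (3 up and 0 down of 27, 3 and 0 adjusted over the list alone, adjusted p = 0.01, and adjusted p = 0.494 with an estimated correlation) was no longer called without replicate 2 at 0 min (0.0795) or replicate 3 at 1 h (0.128). Cytosolic ribosomal proteins (2 up and 0 down of 51, 0 and 0 adjusted over the list alone, adjusted p = 0.01, and adjusted p = 0.627 with an estimated correlation) were no longer called without the same libraries (0.3 and 0.0521). Ncl, Odc1, Cad, Cdk4, Ccnd2, Cdkn1a and Myc did not pass the test. In all, 585 genes rose and 420 fell, or 477 and 576 with scaling by library sums, and falling genes numbered 252 and 206 without replicates 2 and 3 at 0 min and 214 and 266 without replicates 1 and 2 at 1 h.

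At 4 h the largest changes in total exons included Rgcc, P2ry2, Ankrd6, Ccng2, Arntl and Tgfb1i1, which were also among the largest in labelled exons. Rgcc rose by 3.72 ± 0.28 from 29.86 ± 7.55 to 407.4 ± 102 (n = 3 per group), P2ry2 by 2.96 ± 0.18, the adenosine receptor gene Adora2b by 2.72 ± 0.20 and Ankrd6 by 2.68 ± 0.12 (limma adjusted p = 4.02e-16). Stab1, a scavenger receptor gene (Entrez 192187, chromosome 14 from 31952199 to 31981827), rose by 2.52 ± 0.15 from 73.87 ± 9.93 to 428.1 ± 56.8 (adjusted p = 1.12e-13). Ccng2 fell by 1.92 ± 0.10 from 1366 ± 104 to 361.3 ± 35.7 (adjusted p = 5.37e-15), Arntl by 1.89 ± 0.15, the co-chaperone gene Dnajb5 by 1.37 ± 0.13 and Tgfb1i1 by 1.29 ± 0.20. The fall of the actin nucleator gene Lmod1 by 1.53 ± 0.56 (adjusted p = 0.0306) was not called without replicate 1 (0.092) or 2 (0.0851) at 0 min or replicate 3 at 4 h (0.251). Cad and Ccnd2 rose by 0.43 and 0.83. Odc1 stood at 0.25 (adjusted p = 0.0114, 0.0951 without replicate 1 at 4 h, 0.0997 without further scaling, 0.104 with RPKM plus 0.1 and 0.106 with RPKM plus 1). Ncl stood at 0.57 ± 0.19 (adjusted p = 0.0211, and 0.0675 without replicate 2 at 0 min and 0.0607 without replicate 2 at 4 h). Ribosome biogenesis had 30 up and 0 down of 40 (35 and 0 adjusted over the list alone, adjusted p = 3.53e-12, and adjusted p = 0.206 with an estimated correlation). Rrp9 rose by 1.17. In all, 2241 genes rose and 2284 fell, or 1714 and 2834 without further scaling.

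Lists of RNA polymerases and amino acid transporters were called up and mitosis genes down at 4 h in total exons, while polyamine synthesis (adjusted p = 0.209), serine and one-carbon metabolism (adjusted p = 0.136) and cytosolic tRNA synthetases (adjusted p = 0.601) were not called. RNA polymerases I and III had 19 up and 2 down of 33 (19 and 2 adjusted over the list alone, adjusted p = 2.29e-06, and adjusted p = 0.0847 with an estimated correlation) and amino acid transporters 11 up and 0 down of 16 (11 and 0 adjusted over the list alone, adjusted p = 6.7e-05, and adjusted p = 0.0728 with an estimated correlation). The mitochondrial ribosome and transcription list had 12 up and 2 down of 35 (13 and 2 adjusted over the list alone, adjusted p = 0.0019, and adjusted p = 0.398 with an estimated correlation). Translation factors were also called up (adjusted p = 0.00886, and adjusted p = 0.492 with an estimated correlation). Mitosis genes had 1 up and 21 down of 29 (1 and 21 adjusted over the list alone, adjusted p = 3.95e-07, and adjusted p = 0.192 with an estimated correlation). Cenpe changed by -0.57 and Ccnb2 by -0.55. Actomyosin and adhesion genes had 0 up and 8 down of 26 (0 and 5 adjusted over the list alone, adjusted p = 0.0145, and adjusted p = 0.537 with an estimated correlation), a call that ended without replicate 3 at 4 h (0.0769). Purine and pyrimidine synthesis had 14 up and 4 down of 27 (15 and 4 adjusted over the list alone, adjusted p = 0.0211, and adjusted p = 0.543 with an estimated correlation), and its call ended without further scaling (0.0538) and without replicate 2 at 0 min (0.0528) or replicate 3 at 4 h (0.0543). CDK inhibitors and growth arrest genes had 1 up and 6 down of 16 (1 and 6 adjusted over the list alone, adjusted p = 0.0488, and adjusted p = 0.307 with an estimated correlation). Btg2 and the kinase inhibitor gene Cdkn2c changed by -1.04 and -1.02. That call ended with scaling by library sums (0.0554) and without each of 6 libraries, left out with the labelled library of the same time and number. The camera adjusted p was 0.0597 without replicate 1 at 4 h and 0.0595 and 0.0516 without replicates 1 and 3 at 0 min. It was 0.0519 without replicate 3 at 4 h, 0.0521 without replicate 3 at 1 h and 0.0508 without replicate 1 at 16 h.

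At 16 h in total exons Tinagl1 fell by 2.66 ± 0.14 from 4847 ± 726 to 764.2 ± 79.9 (n = 3 per group, limma adjusted p = 3.49e-15), and Tgfb1i1, Arntl and Cldn1 fell by 2.56 ± 0.20, 2.5 ± 0.15 and 2.42 ± 0.12. Slc38a3 and Lingo1, listed at 2.915 ± 2.57 and 1.323 ± 1.15 at 0 min, reached 287.6 ± 30.8 and 98.44 ± 15.4, and Rgcc, Stab1 and Ankrd6 rose by 4.23 ± 0.28, 3.29 ± 0.15 and 3.24 ± 0.12. Myc fell by 1.30 ± 0.20 from 2985 ± 127 to 1225 ± 225, Ncl, Odc1, Cad and Ccnd2 rose by 0.83, 0.59, 0.85 and 0.83, Cdk4 fell by 0.21, and Cdkn1a did not pass the test at -0.18. The Ncl libraries were far apart at 16 h, from 65775.4 to 125368.5, against 48637.3 to 54313.9 at 0 min. Actomyosin and adhesion genes had 0 up and 25 down of 26 (0 and 25 adjusted over the list alone, adjusted p = 1.14e-10, and adjusted p = 0.107 with an estimated correlation). Itga3 changed by -1.29 and the tropomyosin gene Tpm1 by -1.02. Extracellular matrix genes and TGF-beta targets had 0 up and 25 down of 33 (0 and 25 adjusted over the list alone, adjusted p = 1.39e-06, and adjusted p = 0.243 with an estimated correlation). Lox and Sparc changed by -0.76 and -0.71. Ribosome biogenesis had 36 up and 0 down of 40 (36 and 0 adjusted over the list alone, adjusted p = 5.59e-12, and adjusted p = 0.206 with an estimated correlation), and RNA polymerases I and III 23 up and 1 down of 33 (25 and 2 adjusted over the list alone, adjusted p = 8.66e-07, and adjusted p = 0.0731 with an estimated correlation). The mitochondrial ribosome and transcription list had 28 up and 1 down of 35 (29 and 1 adjusted over the list alone, adjusted p = 4.66e-09, and adjusted p = 0.103 with an estimated correlation). Tfb2m rose by 1.23. In all, 3019 genes rose and 3400 fell, or 3405 and 3071 with scaling by library sums.

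Chaperonins and mitochondrial chaperones had 18 up and 1 down of 22 in total exons at 16 h (18 and 1 adjusted over the list alone, adjusted p = 6.26e-05, and adjusted p = 0.364 with an estimated correlation), and heat shock genes 10 up and 1 down of 16 (11 and 1 adjusted over the list alone, adjusted p = 0.00394, and adjusted p = 0.218 with an estimated correlation). Translation factors had 18 up and 4 down of 37 (19 and 4 adjusted over the list alone, adjusted p = 0.00381, and adjusted p = 0.451 with an estimated correlation), purine and pyrimidine synthesis 16 up and 6 down of 27 (18 and 6 adjusted over the list alone, adjusted p = 0.00418, and adjusted p = 0.451 with an estimated correlation) and amino acid transporters 9 up and 3 down of 16 (10 and 3 adjusted over the list alone, adjusted p = 0.00667, and adjusted p = 0.206 with an estimated correlation). Cytosolic tRNA synthetases had 10 up and 2 down of 20 (11 and 2 adjusted over the list alone, adjusted p = 0.045, and adjusted p = 0.599 with an estimated correlation), a call that ended without further scaling (0.0673), with a replicate block (0.0529), and without replicate 3 at 0 min (0.0744) or replicates 1 and 3 at 16 h (0.0588 and 0.0545). Cytosolic ribosomal proteins had 1 up and 18 down of 51 (0 and 14 adjusted over the list alone, adjusted p = 0.0284, and adjusted p = 0.678 with an estimated correlation). Rpsa changed by -0.36 and Rplp0 by -0.34. The call of the list, whose median was -0.11, ended with scaling by library sums (0.0554), without further scaling (0.0723) and without replicate 1 at 0 min (0.148). Markers of other cell types had 4 up and 0 down of 8 (4 and 0 adjusted over the list alone, adjusted p = 0.0266, and adjusted p = 0.112 with an estimated correlation). The macrophage receptor gene Csf1r rose by 1.51 ± 0.16 and the neuronal tubulin gene Tubb3 by 1.69. The unfolded protein response had 4 up and 7 down of 19 (adjusted p = 0.272), with Xbp1 at -1.31, and immediate early genes 3 up and 11 down of 24 (adjusted p = 0.176), with Dusp1 at -1.34.

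**Figure D2:**
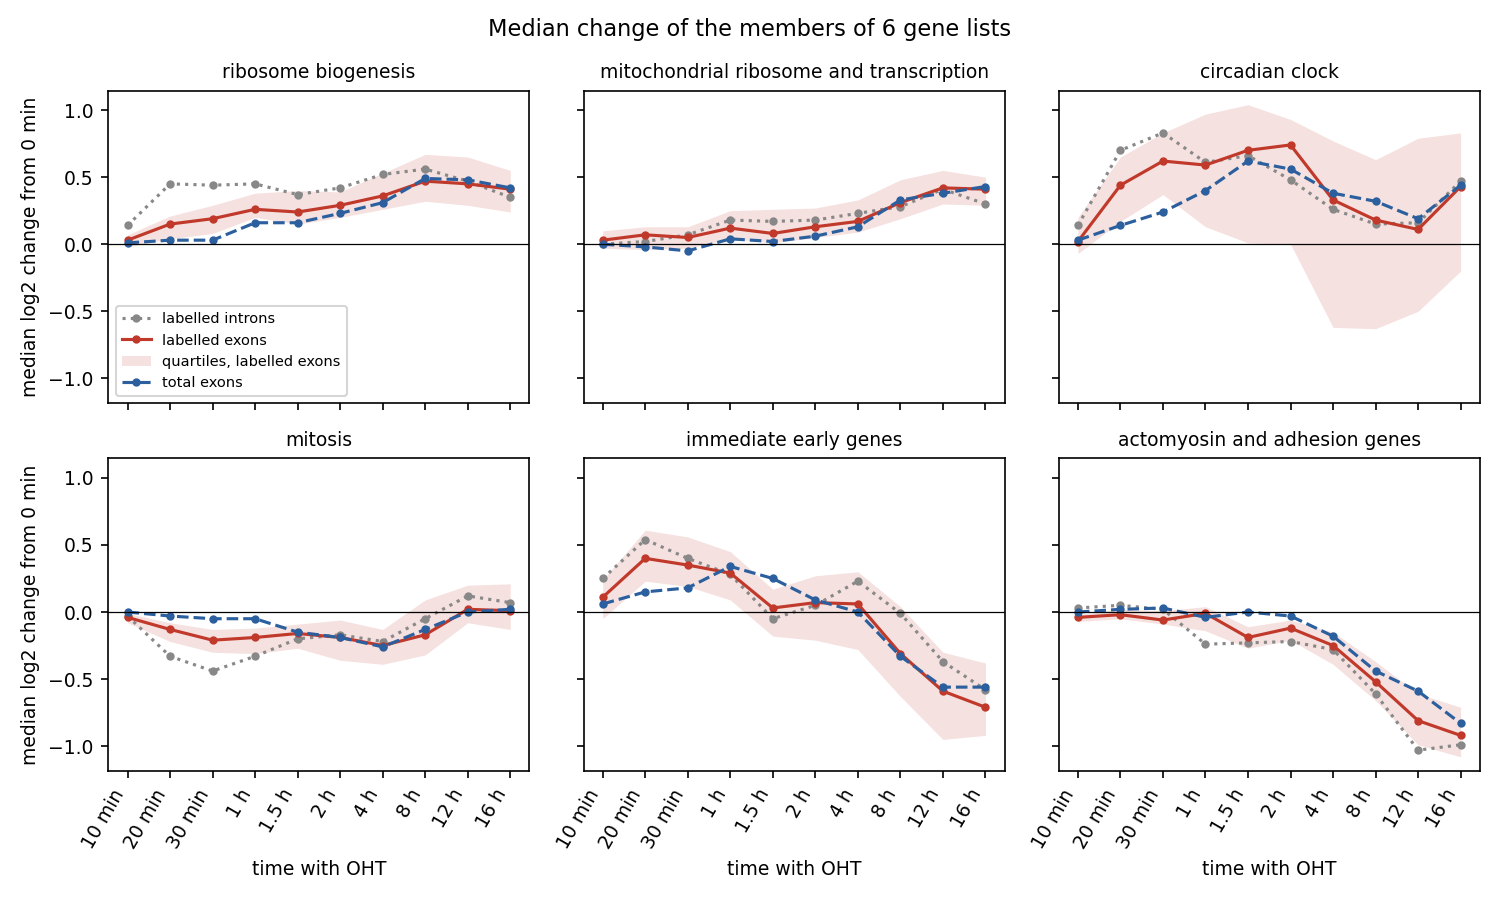
Median log2 change against 0 min (y axis) of the measured members of 6 gene lists at each time after OHT (x axis, times as categories and not to scale), in labelled introns, labelled exons and total exons, with a band for the quartiles of labelled exons. Mitosis genes had a median of -0.25 at 4 h and 0.01 at 16 h in labelled exons, and actomyosin and adhesion genes -0.92 at 16 h.

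Intron values, which come mostly from unspliced RNA, moved before exon values. In labelled introns Nr1d1 had risen by 1.00 ± 0.14 at 10 min (limma adjusted p = 6.36e-05) and by 2.61 at 20 min, against 2.08 in labelled exons and 1.36 in total exons at 20 min. These times of Nr1d1 were picked after its values were seen. At 10 min 60 genes had risen and 0 fallen in labelled introns. The count of rises depended on the setting, with 41 after scaling by library sums, 38 without further scaling, 28 from RPKM plus 0.1 and 5 from RPKM plus 1. Total introns had 14 up and 0 down, or 7 and 1 from RPKM plus 0.1, 0 and 0 from RPKM plus 1, and 1 and 0 with precision weights. Labelled and total exons had 0 genes called by limma (376 and 352 at an unadjusted p under 0.05), or 2 and 1 with a pseudocount of 0.25. At 20 min the called genes numbered 3469 in labelled introns, 463 in labelled exons, 1324 in total introns and 5 in total exons. They were 4879, 1361, 3126 and 42 at 30 min and 5664, 2683, 4662 and 1005 at 1 h. At 4 h labelled introns had 2861 genes up and 2864 down of 11506, and total introns 2268 up and 2310 down of 11474. For the 2241 genes up and 2284 genes down in total exons at 4 h, the log2 difference between the risers and the fallers was followed through the other measures. At 20 min it was 0.493 ± 0.033 in labelled introns, 0.308 ± 0.028 in total introns, 0.187 ± 0.022 in labelled exons and 0.053 ± 0.027 in total exons (± SD, n = 3), against 0.747 ± 0.030 in total exons at 4 h. A gene was called at some time in 7413 cases in labelled exons, 9219 in labelled introns, 8130 in total exons and 8254 in total introns.

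The balance of rising and falling genes at the times between depended on the scaling. In labelled exons 385 genes rose and 78 fell at 20 min, or 238 and 152 without further scaling, 948 and 413 at 30 min, or 491 and 845, and 1694 and 1305 at 1.5 h, or 992 and 2624, where the median of all genes moved to -0.125. The counts were 1792 and 1287 at 2 h, or 1252 and 1797, 2504 and 2583 at 8 h, and 2871 and 2819 at 12 h, or 2053 and 3362. In labelled introns 1903 rose and 1566 fell at 20 min, or 1579 and 1921 with scaling by library sums, 2502 and 2377 at 30 min, or 1809 and 3314 with that scaling, and 2789 and 2875 at 1 h, or 2371 and 3371. At 16 h labelled introns had 2952 up and 2614 down, or 4115 and 1914 with scaling by library sums, which moved the median of all genes to 0.133. In total exons 5 rose and 0 fell at 20 min by limma, or 5 and 1 without further scaling, 3 and 0 with precision weights, and 2 and 0 from RPKM plus 0.1 or plus 1. At 30 min 38 rose and 4 fell, or 25 and 72 without further scaling, 27 and 136 from RPKM plus 0.1, 23 and 157 from RPKM plus 1, and 49 and 7 with a replicate block. Total exons had 1054 up and 901 down at 1.5 h, or 682 and 1395 without further scaling, 1319 and 1208 at 2 h, 2822 and 3058 at 8 h, and 3099 and 3454 at 12 h. In total introns 875 rose and 449 fell at 20 min, or 825 and 249 without further scaling, 1713 and 1413 at 30 min, or 1861 and 907 without further scaling and 1170 and 2155 with scaling by library sums, and 2302 and 2360 at 1 h, or 1744 and 2831 without further scaling. List directions given above are relative to the typical gene in the same way.

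The comparison of labelled with total RNA asked whether the change of a gene's labelled exon values differed from that of its total exon values. At 16 h 13 genes changed more upward in labelled exons and 20 more upward in total exons (limma interaction, 11463 genes, 975 at an unadjusted p under 0.05). Smtnl2, a smoothelin-like gene, stood at 0.44 in labelled and 1.99 in total exons, a difference of -1.59 ± 0.21 (adjusted p = 5.93e-06), and Stab1 rose by 2.05 and 3.29, a difference of -1.28 ± 0.24 (adjusted p = 0.00185). The lysosomal thiol reductase gene Ifi30 differed by -1.14 and the mitochondrial carrier gene Slc25a23 by -1.01. In the other direction, Trp53inp2 stood at -0.45 in labelled and -1.76 in total exons, a difference of 1.27 ± 0.22 (adjusted p = 0.000795). Cdkn3, a phosphatase gene of the cell cycle, stood at -0.04 and -0.97, a difference of 0.89 ± 0.17 (adjusted p = 0.00197). At 4 h 5 genes differed, 4 of them more upward in labelled exons, namely Cln3 (1.69 ± 0.32), Ndufaf3 (1.04 ± 0.22), Gps2 (0.71 ± 0.14) and Pnrc2 (0.67 ± 0.12), and Smtnl2 more upward in total exons (-1.39 ± 0.21, adjusted p = 0.000202). These genes were named after their values were seen. For Smtnl2 and Slc25a23 the labelled exons did not follow the labelled introns. At 4 h their labelled introns stood at 4.51 and 1.87, against 0.56 and 0.39 in labelled exons. The exon test therefore does not show that their new RNA rose less than their total RNA. With same-numbered labelled and total libraries taken as pairs, a fit added after seeing the data, 5 and 2 genes differed at 4 h and 18 and 22 at 16 h. That fit kept 5 of the 5 genes at 4 h and 29 of the 33 at 16 h, including each gene named here. Single libraries decided the counts, since at 16 h the genes more upward in labelled exons numbered 3 without replicate 3 of total RNA at 16 h and 25 without replicate 3 of labelled RNA at 16 h. Those more upward in total exons numbered 10 without replicate 3 of total RNA at 16 h. At 4 h the genes more upward in labelled exons numbered 1 without replicate 3 of total RNA at 4 h and 6 without replicate 1 of labelled RNA at 4 h.

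At the other times, 62 genes were more upward in labelled and 4 more upward in total exons at 20 min, and 179 and 26 at 30 min. The counts were 92 and 44 at 1 h, 69 and 15 at 1.5 h and 19 and 4 at 2 h. At 10 min 0 genes differed by limma (322 at an unadjusted p under 0.05). At 8 h the counts were 13 and 11 and at 12 h 68 and 136. Genes called in both kinds of RNA mostly had the same direction. At 16 h 2252 genes rose in both kinds of RNA where chance placement of the calls would give 688, and 2189 fell in both against 735. At 4 h 1725 rose in both against 439 by chance, 1522 fell in both against 429, and 5 were called in opposite directions against 868. At 1 h 521 rose in both against 80 and 238 fell in both against 41, with 0 called in opposite directions by limma against 114. The 0 min libraries of labelled and total RNA are different libraries, but their same-numbered deviations from the group mean correlated over genes. The correlations were 0.252, 0.205 and 0.0691 at 0 min, 0.299, 0.291 and 0.262 at 4 h, and 0.156, 0.261 and 0.27 at 16 h, so part of the excess may come from shared cultures.

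The intron to exon ratio of labelled RNA asked where unspliced and spliced new RNA moved apart. At 4 h the ratio rose in 124 genes and fell in 124 of 11481 by limma. Smtnl2 had the largest rise of the ratio, by 3.76 ± 0.24 (adjusted p = 1.15e-13), with introns at 4.51 and exons at 0.56, and Zfyve28 and Epor rose by 1.57 ± 0.32 and 1.90 ± 0.52. The ratio of Loxl2, a collagen-crosslinking enzyme gene, fell by 1.56 ± 0.26 (adjusted p = 0.00049), with introns at -1.61 and exons at -0.04, and that of Ccdc82 by 1.30 ± 0.13 (adjusted p = 1.89e-08), with introns at -1.46 and exons at -0.15. These genes were named after their values were seen, and reads of an overlapping or antisense gene cannot be told from those of the intron, because the use of strand is not given in the sources used here. The ratio was called up and down for 842 and 312 genes at 20 min, 1073 and 686 at 30 min, 692 and 597 at 1 h and 41 and 85 at 16 h. At 4 h 38 genes rose and 53 fell without replicate 3 at 0 min, and 44 and 57 without replicate 2 at 4 h, while 72 rose without replicate 3 at 4 h and 78 fell without replicate 2 at 0 min.

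**Figure D3:**
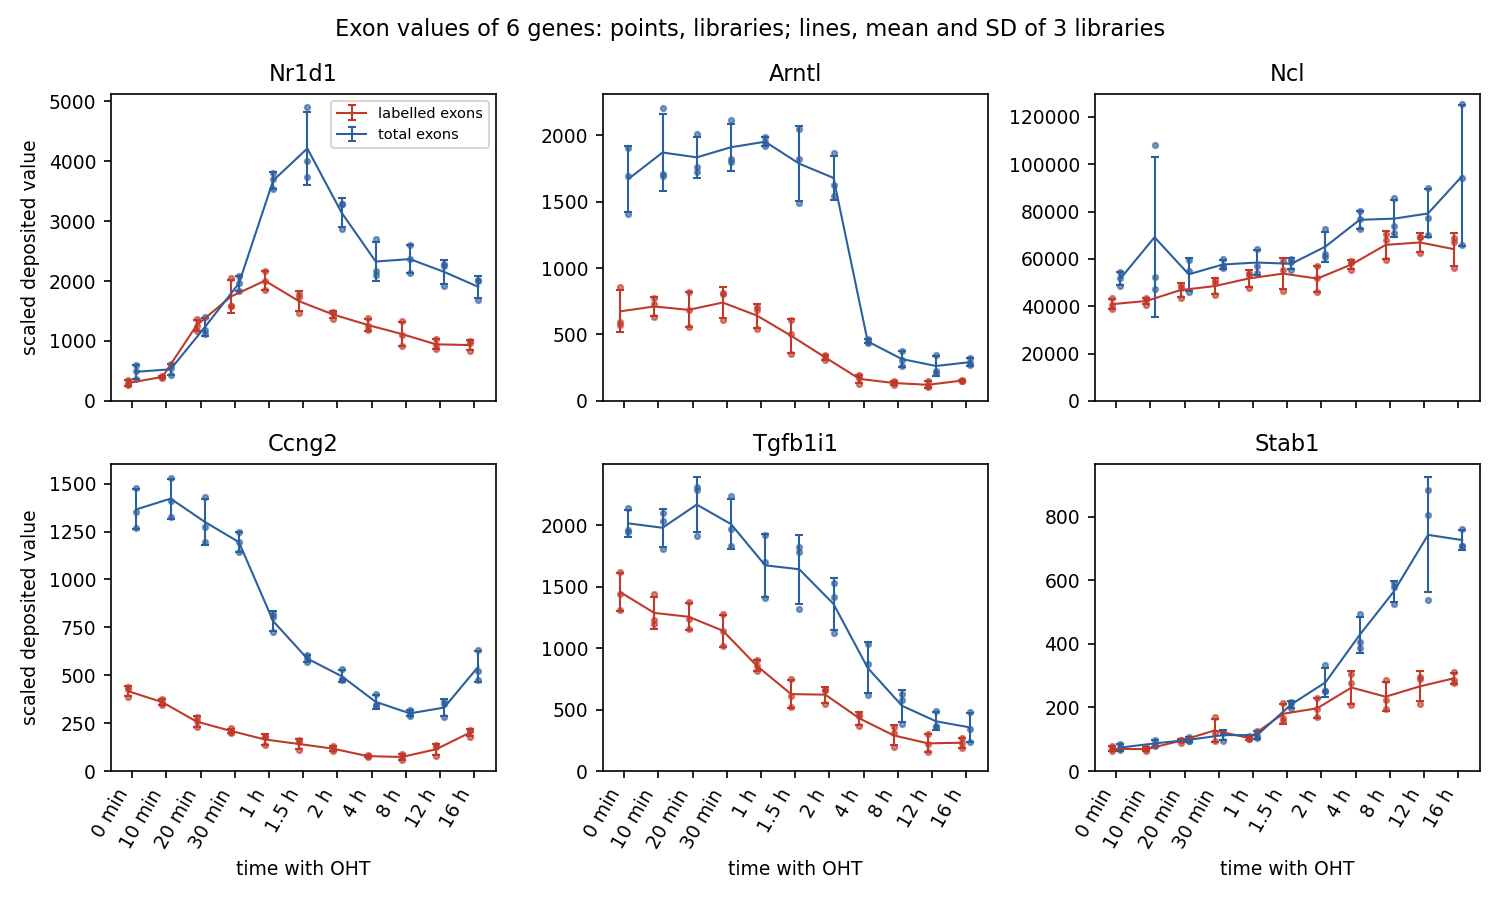
Scaled deposited exon values (y axis, linear scale) of 6 genes in each library of labelled and total RNA (points) at each time after OHT (x axis, times as categories and not to scale), with lines for the mean and bars for the SD of 3 libraries. In labelled exons Nr1d1 went from 299.1 at 0 min to 2006 at 1 h and Arntl from 674 at 0 min to 165.9 at 4 h.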

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

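The test of time in culture for the adhesion and matrix genes, both tests for the clock genes and the fit with pairs were chosen after the result was seen. The others were chosen before. The genes for which the change in labelled RNA differed from that in total RNA were taken up here because the interaction test found a difference between the 2 kinds of RNA. There were 5 such genes at 4 h and 33 at 16 h, and for Stab1, a scavenger receptor gene, the labelled change at 16 h lay below the total change by a difference of -1.28 (limma adjusted p = 0.00185). For each time 100 splits of the libraries were taken, the real one and others drawn at random. Of these, 23 gave at least 5 genes at 4 h and 19 gave at least 33 at 16 h. For the reasons below that count cannot tell whether chance gave the real counts, and chance is not excluded. The highest of the other splits gave 4376 and 7089 genes, many times the real counts. Both were splits that kept the time groups apart in one or both kinds of RNA. Of the splits with as many genes, 20 at 4 h and 18 at 16 h kept the time groups apart in one or both kinds of RNA, so they carry the change over time itself and are no measure of chance. The 79 splits at 4 h that mixed the times in both kinds reached at most 723 genes, and the 81 such splits at 16 h at most 1 gene. Mixing the times puts the change over time into the spread within groups, which lowers the number of calls. The mixed splits therefore do not decide about chance either. With labelled and total libraries taken as pairs, Stab1 kept its call (adjusted p = 0.000189).

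Labelled introns changed before labelled exons. Greater depth of the intron tables would leave the size of the change alike in both, but at 20 min the log2 difference between the genes that later rose and fell in total exons was larger in introns than in exons by 0.306 ± 0.017 (SD, n = 3), which argues against depth as the whole cause. The quotient of the exon to the intron difference rose from 0.379 ± 0.026 at 20 min to 1.073 ± 0.045 at 16 h, a rise of 0.694. That is consistent with exon reads that include RNA made before the change, as carried-over unlabelled RNA or RNA made earlier in the 10 min of labelling would be. How much of each the labelled libraries held was not measured.

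The actomyosin, adhesion and matrix genes, with TGF-beta targets, fell by 16 h relative to all genes. Genes matched on exon length and mean level lay above the 59 members by 0.87, which argues against length or level. Time in culture or growing density cannot be told apart from OHT, because the series has 0 libraries of a time course without OHT. Markers of other cell types rose in total exons at 16 h, with 4 up and 0 down of 8, a median of 0.63 and an adjusted p of 0.0266 (0.112 with an estimated correlation), and a changed cell mix stays open because it was not tested. Repression by MycER may therefore be one hypothesis beside these.

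Clock genes changed early, Nr1d1 from 10 min on in introns. Handling of the cultures stays open as an explanation, because immediate early genes, which respond to handling and serum, had a median change of 0.54 in labelled introns at 20 min (quartiles 0.25 and 0.68, 24 genes), and no mock-treated culture was measured. The hypothesis that a rise of Nr1d1 came before the fall of Arntl had the order it needs, with Arntl called down 80 min after Nr1d1 was called up in labelled introns. This order does not show that one led to the other, and direct action of MycER on either gene may hold as well.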

How the results depend on the processing

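The fit without further scaling, pseudocounts 0.25 and 4, precision weights, library quality weights, the other scalings of the intron to exon ratio and median-of-ratios scaling of the labelled against total comparison were chosen after seeing the data. So were the pairs of labelled and total libraries and all settings of the list tests other than the estimated correlation and the replicate block. The remaining settings were chosen before. The planned count-model alternative and voom with sample weights were not run, because both need raw counts. No result named here changed its direction past the threshold. With 1 library left out, 144 counts of the main comparisons stayed within 1.5 times and 24 did not. Among them, the counts over all times were made without all libraries of 1 replicate number instead. With other settings 260 stayed and 12 did not, and the cause was not tested. Single-gene calls were lost in 313 of the fits with 1 library left out and in 198 of those with other settings. In 5338 and 10149 of these fits the gene kept its state. They include genes called in neither fit, so not all of them are kept calls. For the 80 largest changes 1357 of 1360 fits stayed and 3 calls were lost. Of 783 named calls, 37 were lost without further scaling, 20 with scaling by library sums, 4 with median-of-ratios scaling, 47 and 45 with the RPKM values plus 0.1 and plus 1, and 33 in fits of the 6 compared libraries alone. The RPKM fits also had no further scaling, so their losses are not independent of the 37. Changes near the pseudocount depend on it most, and since true read depth is unknown, how far depth limits the low genes cannot be given.

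For the change in labelled against total exons, 8 genes at 4 h were more upward in labelled and 3 in total exons with the replicate block, and 20 more upward in labelled exons at 16 h. With the replicate block set by pairs of labelled and total libraries the counts were 5 and 2 at 4 h and 18 and 22 at 16 h. Without further scaling they were 8 and 2 at 4 h and 20 more upward in labelled exons at 16 h. A pseudocount of 0.25 gave 7 and 2 at 4 h, no filter on low values 23 more upward in labelled exons at 16 h, and library quality weights 27. With 1 library left out the counts ranged from 1 to 6 and from 1 to 3 at 4 h, and from 3 to 25 and from 10 to 26 at 16 h. The intron to exon ratio at 4 h had 215 genes up with scaling by library sums, and from 38 to 106 up and from 53 to 96 down with 1 library left out. Genes down in total exons at 1 h ranged from 206 to 320 with 1 library left out. With a correlation estimated from the data, 9 of the 65 called list tests were called. With the labelled and the total library of 1 time and number left out together, the number of called list tests ranged from 62 to 70.

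With the replicate block 2441 genes rose and 2572 fell in total exons at 4 h, where the numbers pair the libraries, and 2373 and 2496 in total introns at 4 h. There the block ended no call of a list or named gene and moved no count by over 1.5 times. At 30 min, where the numbers pair total exons too, it gave 49 and 7 in place of 38 and 4, and at the other paired times it moved no count by over 1.5 times. In the other main comparisons the samples shared only a number. There the correlations of same-numbered deviations were 0.395, 0.244 and 0.00801 in labelled exons at 1 h, 0.237, -4.41e-05 and -0.121 at 4 h, and 0.121, 0.162 and -0.0836 at 16 h. They were -0.313, 0.279 and 0.116 in total exons at 1 h, 0.0902, 0.35 and 0.218 at 16 h, and 0.286, -0.0157 and -0.0919 in labelled introns at 4 h. As a hint from the data, every library correlated best with its own number only in total exons at 16 h among these. The block gave 1708 and 1225 calls at 1 h, 2385 and 2305 at 4 h and 2725 and 2569 at 16 h in labelled exons, 742 and 564 at 1 h and 3186 and 3572 at 16 h in total exons, and 2923 and 2952 in labelled introns at 4 h. Among the list tests 66 were called with the block, 64 of them shared, and the call of cytosolic tRNA synthetases in total exons at 16 h ended (0.0529).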

Other observations

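The tests here were chosen before their results were seen, but the genes named here were chosen after their values were seen. Txnip, which encodes a binding protein of thioredoxin that restrains glucose uptake, was a late riser. In labelled exons it changed by -0.49 at 20 min, which did not pass the test, and rose by 2.15 ± 0.20 at 12 h (limma adjusted p = 4.92e-11) and 2.06 at 16 h, with 1.86 in total exons at 16 h. The clock output gene Dbp rose by 0.83 ± 0.22 in labelled introns at 20 min (adjusted p = 0.00372) and by 1.58 in total exons at 16 h. Per1 and Per2, which encode repressors of the clock, rose early in labelled introns, by 0.61 and 0.70 at 20 min, and then changed by -0.66 and -0.53 at 4 h (adjusted p = 0.000219 and 0.0099). At 16 h they stood at -0.07 and 0.30, which did not pass the test. Tubb3 rose by 0.86 in labelled introns at 20 min (adjusted p = 0.000425) and by 1.83 in labelled exons at 16 h. The immediate early genes Egr1 and Fos did not pass the test in labelled introns at 20 min, with changes of 0.48 and 0.56.

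Early intron changes went with late changes of total RNA. Of 1902 genes up in labelled introns at 20 min, 1260 were up and 147 down in total exons at 16 h, where independent lists would give 500 and 563 of 11479 genes, and the quotient of 8.57 is consistent with early changes of introns being carried into total exons. Of 1565 genes down at 20 min, 702 were down and 172 up at 16 h, against 463 and 412. The libraries differ between the 2 comparisons, but the cultures at 0 min may be shared, so part of the excess may come from them.

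Esr1, the oestrogen receptor gene whose ligand-binding part is in the fusion gene, had labelled exon values of 6719 ± 1060 at 0 min (SD, n = 3) and intron values of 21.59 ± 2.85. Its exon to intron quotient lay at percentile 99.99 of 10019 genes. In labelled exons it fell by 0.80 at 16 h (limma adjusted p = 3.32e-05) to 3852 ± 430. Exon values so far above the intron values argue against transcription of the endogenous gene as their main source. No read was assigned to either gene, so the share of fusion reads is not given.

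Other splits of the libraries into groups of the same sizes were counted for each result. Over all times, among 100 splits only the real 1 gave as many genes. Library labels were shuffled singly, so chance differences between cultures are not excluded if the libraries of a time shared a culture. Labelled exons had 7413 called genes against at most 1851 in other splits, labelled introns 9219 against 1062, total exons 8130 against 3099, and total introns 8254 against 546. For the other times the sum of calls was 89896 against 8522, again with 1 of 100 splits.

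For a single time 3 libraries against 3 make 10 splits, too few for a share under 0.05. The real split, which was 1 of 10 with as many genes in each case, gave 2683, 4402 and 5094 genes in labelled exons at 1 h, 4 h and 16 h, 1005 and 4525 in total exons at 1 h and 4 h, 5725 and 4578 in labelled and total introns at 4 h, and 1154 and 248 for the intron to exon ratio at 20 min and 4 h, each against at most 0 in the other splits by limma. In total exons at 16 h it gave 6419 against at most 1. Among the splits that part as many pairs, the highest was 0 in total exons and 0 in total introns at 4 h.

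For the gene list tests with the preset correlation, another split called more lists than the real one in every comparison except labelled exons at 1 h. The number of called lists therefore did not set the real grouping apart there, and again 10 splits are too few. Here adjustment ran within each comparison. In labelled exons the real split called 14 lists at 1 h against at most 10, 10 at 4 h against 15 and 11 at 16 h against 18, and 1, 3 and 4 of the 10 splits gave as many. In total exons it called 9 lists at 1 h against at most 11, 8 at 4 h against 14 (11 among splits parting as many pairs) and 13 at 16 h against 15, and 5, 6 and 2 of the 10 splits gave as many.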
